A study of Mus musculus with 2 samples.

How the data were processed

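Total RNA of the thymus of 2 newborn mice (postnatal day 0), both lobes of each pup, was sequenced as 1 library per pup. Per the labels' protocols, RNA was extracted with a mirVana kit, 10 ng entered each library, molecules above a stated size limit were kept, spike-in RNA was added and a kit manual for low RNA input was cited. The groups and replicate numbers came from the labels, which name both pups as pups of 1 pregnant female. The samples are therefore separate animals of 1 litter, and the spread between them holds biological and technical parts together.

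For each library the authors deposited 1 table of genes and 1 of transcripts. Expected counts, which are estimated counts that need not be whole, were deposited by the authors without normalization. The deposited TPM values are relative to transcript length and to the sum over all transcripts of a library, and the deposited FPKM values are relative to transcript length and library size. The percent of a gene's TPM assigned to each transcript was also deposited, in the transcript tables. Per the labels the genome build is mm10, and per the deposited read-me texts the annotation is M4. The aligner, the quantifier and the use of strand are not given in the sources used here. Effective lengths were 99 nt shorter than transcript lengths for 100% of transcripts of 100 nt or more. Without knowledge of strand, reads of a gene and of an overlapping antisense gene could not be told apart, and reads of near-identical genes were divided by the authors' estimate.

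Each gene table held 69691 rows: 43346 genes, 96 ERCC spike-ins, 1 phiX row and 26248 rows whose identifier is only a number. The last 3 kinds were left out of gene totals and tests. Rows with a number as identifier held 0.000105% and 0.0000404% of counts. Gene symbols, biotypes and coordinates were taken from GENCODE M21 (GRCm38) by gene identifier without version, which matched 42462 gene rows. The 884 others held 0.266% and 0.225% of counts. Of 129984 transcripts, 101510 matched. GC content and length were available for 99.6% of detected genes. Of 334 genes in the 39 lists, 331 were measured, and 3 (Trdc, Ahsp and Snhg1) were not analysed here.

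Depth was 39046411 and 41576822 expected counts. A gene with 0 counts could have had up to 3. Intervals are 95% Wilson intervals. Those of the spike-ins, like this floor, cover counting error only, because reads without molecular identifiers are not independent molecules, and that of the shared highest transcript takes genes as independent, which they are not. Spike-ins held 16.9 (15.6 to 18.2) and 10.3 (9.34 to 11.3) CPM, a mean of 13.6 ± 4.67, and the coefficient of variation of 10 spike-ins beyond counting error was 9.35%. Expected counts were rounded to whole numbers for edgeR and DESeq2. A chi-square statistic over 17258 genes was 19.5 times its degrees of freedom, which argues only against 1 library deposited under both labels. That they are biological replicates rests on the labels.

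A gene was called detected at TPM of at least 1 in both libraries. Library sizes were scaled with edgeR's TMM method (version 4.0.16, R 4.3.3), and the biological coefficient of variation is the square root of edgeR's common dispersion after filterByExpr. Log2 ratios are replicate 2 over replicate 1 with a prior count of 0.5, counted as over 2-fold at a mean expected count of at least 50. List differences used members with a mean count of at least 10. The percentile of each list's median among 10000 random lists of the same size matched on mean expression describes these libraries and is no test of a condition. The same number of random lists, unmatched, placed the level of each list. With 1 group, no test between groups was possible. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

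The lists, the thresholds and the rule for named genes were fixed before the data were examined. The text may name the 3 highest members of each list and members below 1 TPM, any member of the receptor, rearrangement, double-positive, transcription factor and epithelial lists, the 15 highest of all genes, the 10 largest differences in each direction at a mean count of at least 100, the sex-linked list, and 8 genes for isoforms. Adipoq, Hbb-y, Pdgfra, Kcnq1ot1, Neat1 and Meg3 were named outside this rule after their values were seen. Alternatives changed the detection threshold, the unit, the scaling (DESeq2 1.42.0, spike-ins, TPM), the filters and pseudocount, and used each library alone. Removal of the trends with transcript length and GC content, and other treatments of copied V segments, were added after seeing the data.

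The steps were tested on simulated data for the comparison of replicate 2 with replicate 1, drawn from the means of 43346 genes. Of the genes changed 4-fold 100% were found over 2-fold in the right direction, of those changed 1.5-fold 7%, and of 13953 unchanged genes 0.0287%. A spread of 11.7% was recovered as 11.5% without changed genes (17484 genes) and as 14.2% with 200 changed genes. A list of 8 genes raised 4-fold stood at percentile 100 and 8 unchanged genes at percentile 54.9.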

Results

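Total RNA was sequenced from the thymus of newborn mice (postnatal day 0, strain B6NCrl), the organ in which T cells mature and rearrange their receptors. The 2 libraries came from both thymus lobes of 2 pups of 1 pregnant female, so they form 1 group of 2 biological replicates. The labels name no treatment or other tissue. The question addressed is therefore which genes a newborn thymus expresses and how far 2 littermates differed. The libraries held 39046411 (replicate 1) and 41576822 (replicate 2) expected counts. Levels are TPM, a length-scaled relative abundance, given as mean ± SD over both libraries (n = 2) unless both values are given, and coordinates are GRCm38 (mm10). No p-value across genes was computed, because genes are not replicates.

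Genes of the T-cell receptor and its signalling partners were among the most abundant in the tissue. All 7 measured members of the T-cell receptor and CD3 complex list were detected (TPM of at least 1 in both libraries), with a list median of 500.4 TPM. The beta-chain constant regions Trbc2 (chromosome 6, 41546730 to 41548352) and Trbc1 reached 5105 ± 69.4 and 3008 ± 10.7 TPM. Their sequences are near-identical, so the split of reads between them is uncertain. The alpha-chain constant region Trac reached 500.4 ± 32.0 TPM, and the CD3 chains Cd3g, Cd3d and Cd3e reached 817 ± 31.2, 476 ± 24.1 and 414 ± 50.7 TPM. In the T-cell receptor signalling list all 11 members were detected, with a median of 99.97 TPM. Its highest members were the kinase Lck at 1239.8 ± 29.4 TPM, the adaptor Lat at 574 ± 23.1 TPM and the phosphatase Ptprc (CD45) at 348 ± 19.7 TPM.

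Genes of receptor rearrangement and of the CD4 CD8 double-positive stage were detected without exception among the measured members. The V(D)J recombination and pre-TCR list (10 of 10 detected) had a median of 70.7 TPM. It held the recombinase genes Rag1 at 271 ± 11.7 and Rag2 at 105 ± 16.7 TPM, the terminal transferase Dntt at 113 ± 6.97 TPM and the pre-receptor chain Ptcra at 98.4 ± 1.92 TPM. The double-positive list (9 of 9) had a median of 219 TPM, with Cd8b1 at 1041 ± 30.3, Cd8a at 380.2 ± 5.56, the chemokine receptor Ccr9 at 404 ± 46.1 and Cd4 at 84.1 ± 0.467 TPM. All 14 T-lineage transcription factors were detected at a median of 91.1 TPM. Tcf7 was the highest at 972 ± 114 TPM, followed by Satb1 at 668 ± 96.4 TPM. Runx3 and Zbtb7b, factors of the CD8 and CD4 lineages, were the lowest at 5.24 ± 1.80 and 3.58 ± 0.332 TPM.

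Lists of earlier and later thymocyte stages lay below these levels. Early progenitor genes (13 of 13 detected) had a median of 9.09 TPM, led by Notch1 at 41.0 ± 5.95, the interleukin-2 receptor chain Il2ra at 40.1 ± 3.19 and Dtx1 at 34.0 ± 0.594 TPM. Mature single-positive genes (10 of 10) had a median of 36.4 TPM, led by Cd27 at 176 ± 44.3 TPM. The regulatory T-cell list had a median of 9.76 TPM with 5 of 6 members detected. Its defining factor Foxp3 was at 0.0900 and 0.110 TPM, from 9 and 12 counts. In the gamma-delta and innate-like list 7 of 9 measured members were detected, with a median of 15.2 TPM. The gamma-chain constant regions Tcrg-C1 and Tcrg-C2 stood at 260.4 ± 55.6 and 176 ± 44.4 TPM, while the innate-like factor Zbtb16 (0.760 and 0.870 TPM) and the cytokine Il17a (0.470 and 0.320 TPM) lay below 1.

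Dividing-cell genes were high: all 12 cell cycle genes were detected, with a median of 203 TPM and Pcna, Rrm2 and Birc5 at 392 ± 6.18, 392 ± 10.1 and 387 ± 11.1 TPM. Replication-dependent histones (12 of 13 detected) had a median of 32.3 TPM, and Hist2h3c1 had 0 and 41 counts. Histone genes are near-identical copies, so their levels are uncertain. Apoptosis regulators (8 of 8) had a median of 45.0 TPM, with the survival gene Bcl2l1 at 147 ± 0.962 and the death effector Bax at 136 ± 0.643 TPM. Glucocorticoid response genes (5 of 6) had a median of 32.3 TPM, led by Fkbp5 at 97.6 ± 5.13 TPM, and immediate-early and heat shock genes (9 of 10) had a median of 14.3 TPM, led by Ier2 at 67.3 ± 5.01 TPM.

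Cortical epithelium, the stroma that selects thymocytes, gave a list median of 373 TPM with 12 of 12 members detected. The protease Ctsl (1624 ± 54.0 TPM), the keratins Krt18 (1106 ± 30.6 TPM) and Krt8 (1002 ± 6.33 TPM) and Tbata (691 ± 194 TPM) led it. The chemokine Ccl25 (679 ± 13.6 TPM) and the serine protease Prss16 (540 ± 22.7 TPM) were also high. Ctsl, Krt8 and Krt18 are also expressed by other cell types. Medullary epithelium had a median of 16.2 TPM with 12 of 13 detected. The chemokine Ccl21a stood at 355 ± 25.8 TPM, Krt5 at 93.8 ± 3.50 TPM, the tolerance regulator Aire at 7.78 ± 0.792 TPM and Fezf2 at 4.68 ± 0.679 TPM, while the costimulator Cd80 was at 0.340 and 0.450 TPM. Of 8 tissue-restricted self-antigen genes, which Aire or Fezf2 can induce, 5 were detected. The casein gene Csn2 led them at 31.8 ± 2.84 TPM. Csn1s2a, Cyp1a2 and Crp were below 1 TPM in at least 1 library.

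Other cells of the organ were seen at varied levels. Mesenchyme genes (10 of 10 detected) had a median of 38.7 TPM, led by Col3a1 at 154 ± 15.2 TPM, and endothelial genes (8 of 8) had a median of 6.26 TPM, led by Pecam1 at 50.6 ± 0.813 TPM. Antigen presentation genes of MHC class II (7 of 7) had a median of 404 TPM, with Cd74 at 1620.3 ± 14.1 TPM. Macrophage genes (10 of 10) had a median of 20.8 TPM, with the complement gene C1qb at 106 ± 5.39 TPM, and dendritic cell genes (6 of 9) had a median of 2.14 TPM. B-cell genes (4 of 9) had a median of 1.04 TPM. Within that list Ighm was at 283 ± 13.1 TPM, whereas Ms4a1 was at 0.235 ± 0.00707 TPM. NK-cell genes (5 of 6) had a median of 2.00 TPM with Gzma, a granzyme also made by T cells, at 295 ± 29.3 TPM. In the erythroid list (6 of 10) the adult globins Hba-a2 and Hbb-bs reached 1316 ± 105 and 773 ± 51.3 TPM and the embryonic globin Hbb-y 1.86 ± 0.262 TPM. The median of that list was 4.37 TPM.

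Genes of organs that lie near the thymus were mostly low. Parathyroid genes had a median of 8.05 TPM (10.5 and 5.60 in replicates 1 and 2), with parathyroid hormone (Pth) at 41.5 ± 18.9 TPM, although its regulator Gcm2 was at 0.05 TPM in both libraries. Adipose tissue genes had a median of 2.17 TPM (3.75 and 0.580), with 3 of 7 detected and Fabp4, also expressed by endothelium and macrophages, at 224 ± 49.7 TPM. Medians were 3.48 TPM for skeletal muscle (2.5 and 3.93, 5 of 7 detected), 2.41 TPM for cardiac muscle (3 of 5), 0.985 TPM for lung and airway (2 of 4), 0.165 TPM for Schwann cells (0 of 5) and 0.10 TPM for thyroid (0.06 and 0.15, 1 of 5). Granulocyte and mast cell genes had a median of 4.52 TPM (5.49 and 2.77) with 8 of 9 detected, led by S100a8 at 103 ± 28.7 TPM. Of the sex-linked genes, Xist was at 39.9 and 27.6 TPM. Among the Y-linked genes, Ddx3y, Eif2s3y and Uty had 0 counts in both libraries, and Kdm5d had 0 and 1 count. A count of 0 allowed up to 3 counts, or 0.0768 and 0.0722 CPM.

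**Figure D1:**
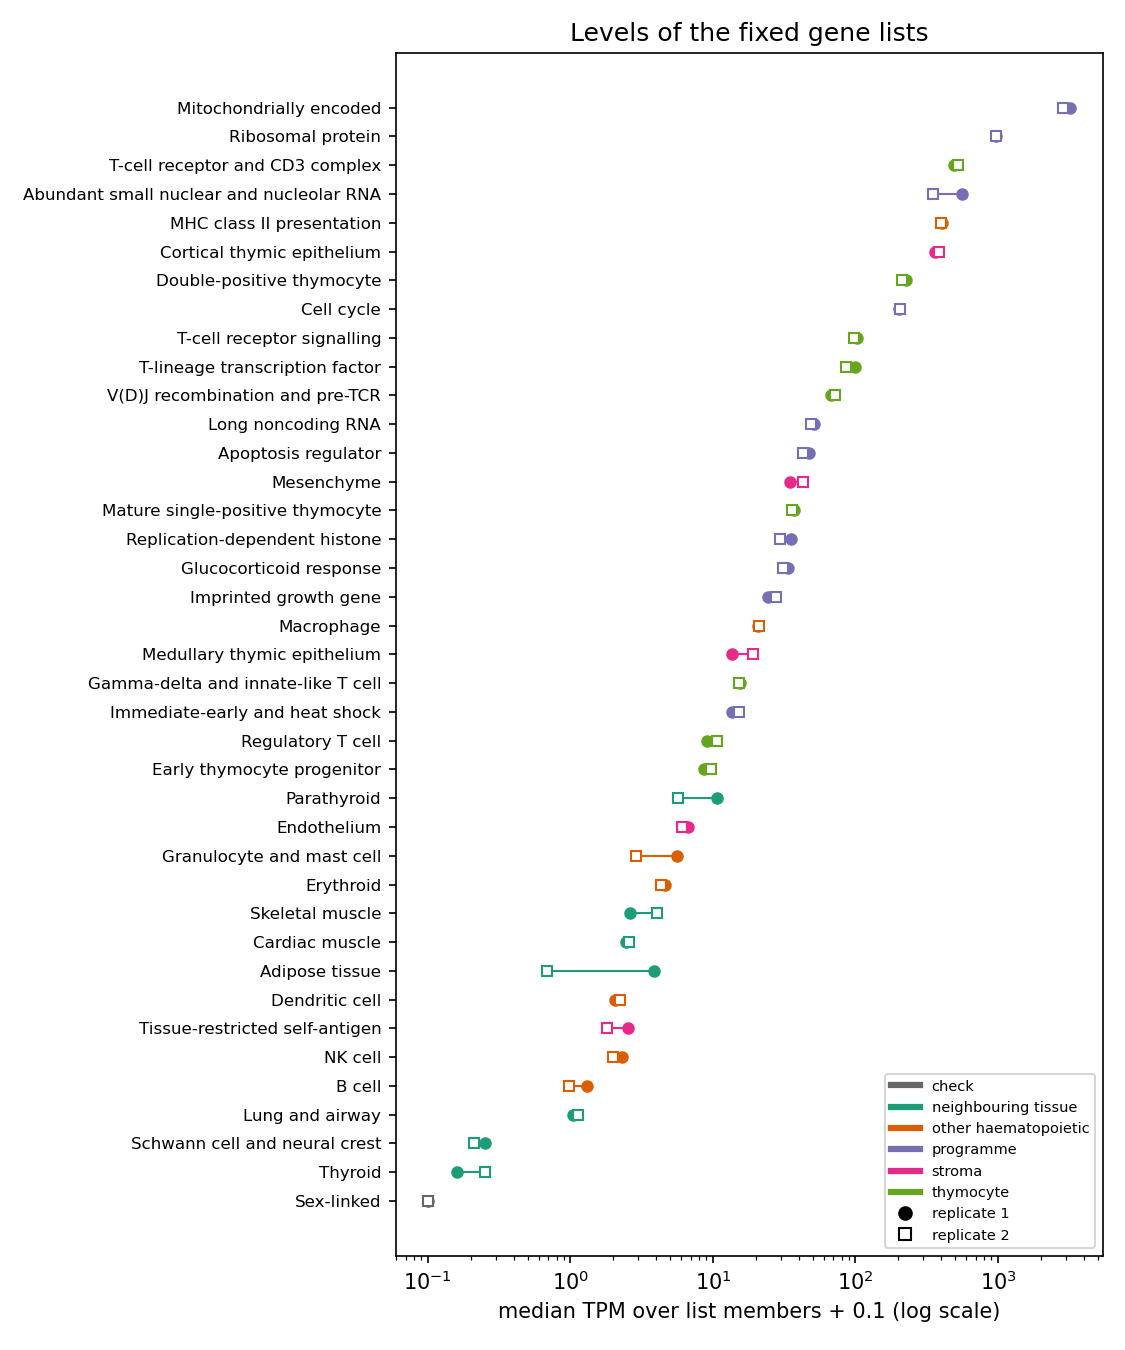
Median TPM over the members of each of the 39 gene lists (horizontal axis, log scale, 0.1 added) in replicate 1 (filled circles) and replicate 2 (open squares), coloured by kind of list. The T-cell receptor and CD3 complex (493 and 523 TPM) and cortical thymic epithelium (360.3 and 387 TPM) lie high in both libraries, while adipose tissue (3.75 and 0.580 TPM) is far apart.

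Over all genes, 13957 were detected. Protein-coding genes held 83.0% ± 0.712 of TPM, pseudogenes 6.53% ± 0.169, T-cell receptor segments 1.36% ± 0.0308 and long noncoding genes 2.46% ± 0.539. The long noncoding share includes Gm42418, 1 of the 10 highest genes, at 8483 and 5760 TPM in replicates 1 and 2. What kind of RNA its reads came from was not tested. The highest 10 genes held 11.3% ± 0.159. The signal recognition particle RNAs Rn7s2 and Rn7s1 were highest at 22519 ± 586 and 22517 ± 583 TPM, followed by Actb at 9922 ± 546, mt-Atp6 at 9739 ± 525 and the histone Hist1h2ap at 9488 ± 527 TPM. Rn7s1 and Rn7s2 are near-identical, and Gm28437 (8863 ± 638 TPM), an annotated pseudogene on chromosome 1, and Gm10123 (5619 ± 362 TPM), a processed pseudogene, may share reads with their parent genes, so these levels are uncertain. Genes annotated on the mitochondrial genome held 4.70% ± 0.00490 of TPM, and the mitochondrially encoded list (10 of 10) had a median of 3158 TPM. The 4.70% leaves out any mitochondrial reads assigned to pseudogenes on other chromosomes, which would be counted in the pseudogene share. Ribosomal protein genes (14 of 14) had a median of 963 TPM, led by Rps14 at 2734 ± 81.2 TPM. The list named small nuclear and nucleolar RNA (7 of 7), which also holds Rn7s1 and Rn7s2, had a median of 456 TPM (562 and 350.4). Medians were 49.9 TPM for long noncoding RNA (6 of 7) and 25.4 TPM for imprinted growth genes (10 of 10).

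Of the 6065 genes with at least 2 annotated transcripts and a mean of at least 10 TPM, 94.6% (95% Wilson interval 94.0 to 95.1 over genes, which are not independent) had the same highest transcript in both libraries. Tcf7 was assigned mainly to transcript Tcf7-201, at 91.2% ± 0.113 of its TPM, and Ikzf1 to Ikzf1-204, at 78.4% ± 0.113. Lef1-201 took 67.6% ± 0.983 of Lef1, Cd44-207 took 61.1% ± 3.52 of Cd44, and Ptprc-203 took 57.1% ± 2.79 of Ptprc. Lck was divided over Lck-201 (48.5% ± 1.07), Lck-202 (22.0% ± 2.96) and Lck-207 (19.1% ± 4.54), which is annotated as a retained intron. Bcl2l1-201 and Bcl2l1-202 held 47.5% ± 2.21 and 39.2% ± 0.863 of Bcl2l1, and Runx1-201 and Runx1-202 held 38.95% ± 2.38 and 34.8% ± 0.481 of Runx1. These shares depend on the transcripts annotated.

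The libraries of the 2 pups were close for most genes, with exceptions that included Krt4, Krt13, Krt15 and Eln. Across 14987 genes at TPM of at least 1 in either library, log2(TPM + 1) gave Pearson r = 0.987 and Spearman rho = 0.986, as a relation across genes, which are not independent. Among 14155 genes with a mean expected count of at least 50, 191 differed over 2-fold, 163 higher in replicate 1 and 28 higher in replicate 2. With minimum counts of 10 and 500 the number was 840 and 21. The 163 include provisional (TEC) and sense-intronic gene models. At the minimum of 50, 109 of 118 such models were higher in replicate 1, at a median log2 ratio of -0.98. How many of the 163 they make up was not counted. The median absolute difference was 1.10-fold. The biological coefficient of variation was 11.7% over 17258 genes. Despite its name it holds technical spread as well. For 10 spike-ins, which hold a technical part only, the value beyond counting error was 9.35%. How much of the 11.7% is biological was not tested. Scaling on the spike-ins, which had 659 and 427 counts, instead of on the genes moved the median log2 ratio of all genes from 0.02 to 0.71. The split was then 30 higher in replicate 1 and 977 higher in replicate 2, so all differences between libraries given here are relative to the bulk of genes.

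Among the 10 largest differences higher in replicate 1 were 3 keratins. Krt4 (chromosome 15, 101918535 to 101924735) had 35.8 TPM in replicate 1 and 0.990 TPM in replicate 2, from 2144 and 64 counts. Krt13 had 14.96 and 0.580 TPM, Krt15 had 29.2 and 4.28 TPM, and the carbonic anhydrase Car3, abundant in fat and muscle, had 19.3 and 1.07 TPM. Cyp2f2, Xlr3b, Zfp965, 3830403N18Rik and 2300002M23Rik were also among these 10, at 4.60- to 25.6-fold, and the largest was the pseudogene Rpl7a-ps11, with 264 and 0 counts. The 25.6-fold of Zfp965 came from 237 and 9.21 expected counts, while its TPM differed less, at 7.02 and 1.17. The keratins Krt5 (96.3 and 91.3 TPM) and Krt14 (39.6 and 34.0 TPM) differed little. Higher in replicate 2 were elastin (Eln, chromosome 5, 134702593 to 134747323), at 9.15 and 71.4 TPM and 8.05-fold, and Eps8l1, at 0.680 and 4.93 TPM. By scaled counts, from which all folds here are taken, Eps8l1 differed 10.8-fold (23 and 265 counts). The other 8 of the 10 largest differences in that direction, Hist1h2aj, Itga8, Mtus2, Gm8226, Gm21541, Zfp993, Gm28592 and Zfp973, were between 2.00- and 2.20-fold. Several of the genes named in both directions, such as Rpl7a-ps11, Zfp965, Xlr3b, Gm8226 and Zfp973, are pseudogenes or members of repeated families whose reads are hard to assign.

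**Figure D2:**
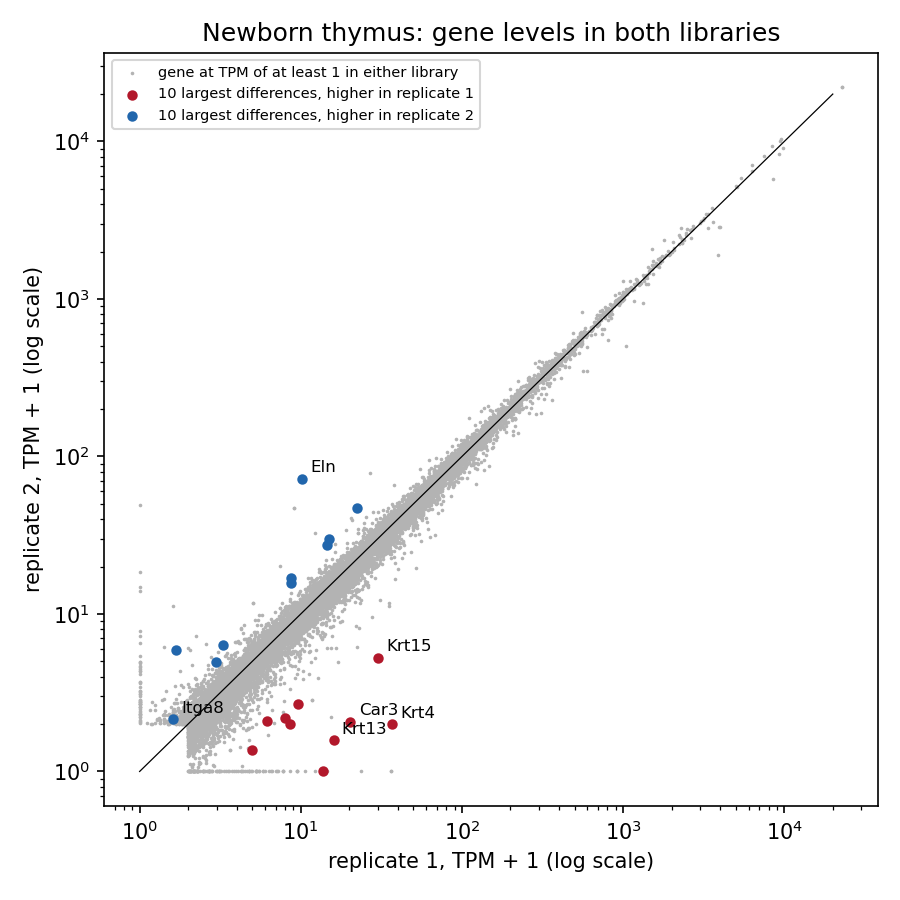
TPM + 1 of each gene in replicate 1 (horizontal axis) and replicate 2 (vertical axis), both on log scales, for genes at TPM of at least 1 in either library, with the line of equal values. Krt4 (35.8 and 0.990 TPM) and Eln (9.15 and 71.4 TPM) lie far from that line.

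Of the 36 lists with at least 3 members above 10 mean counts, 11 had a median difference outside the central 95% of 10000 random lists matched on expression. If members varied independently, 1.8 would be outside. Members of 1 list can vary together and some lists share genes, so the 2 numbers are a description and no test. Higher in replicate 1 were adipose tissue (7 of 7 members, median 1.94-fold), granulocytes and mast cells (6 of 9, 1.84-fold), parathyroid (3 of 3, 1.83-fold), long noncoding RNA (5 of 7, 1.28-fold), replication-dependent histones (11 of 13, 1.15-fold) and T-lineage transcription factors (9 of 14, 1.06-fold). Adiponectin (Adipoq) had 3.75 and 0.580 TPM, Pth had 54.9 and 28.2 TPM, S100a9 had 41.2 and 21.7 TPM, and the nuclear RNA Malat1 had 3907 and 1892 TPM, from 50220 and 26517 counts. The TPM of Malat1 depends on the assignment of 99.2% of it to a transcript of 485 nt, beside an annotated one of 6983 nt. Under spike-in scaling the long noncoding, histone and transcription factor lists turned to higher in replicate 2, with medians of 0.34, 0.48 and 0.60 on the log2 scale. That scaling adds the same amount to each ratio, and their percentiles stayed at 0.02, 1.32 and 0.06, so they remained low relative to matched lists. With the trends of transcript length and GC content removed, long noncoding RNA moved inside the central 95%, at a median of -0.11. That move came from 1 member, Kcnq1ot1 (-0.92 before and -0.11 after), while Malat1 stayed at -0.99. Beside these lists, transcripts annotated as retained introns held 4.40% of TPM in replicate 1 and 3.95% in replicate 2.

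Higher in replicate 2 were skeletal muscle (7 of 7 members, 1.58-fold), imprinted growth genes (7 of 10, 1.23-fold), mesenchyme (10 of 10, 1.18-fold), glucocorticoid response (4 of 6, 1.14-fold) and cortical thymic epithelium (11 of 12, 1.10-fold). Acta1, the skeletal actin, had 11.97 and 18.4 TPM, and Col3a1 had 144 and 165 TPM. Among cortical genes Tbata had 554 and 828 TPM, the thymoproteasome subunit Psmb11 67.7 and 97.0 TPM and the epithelial master regulator Foxn1 18.4 and 27.4 TPM, while Krt8, Ccl25 and Ly75 differed by at most 1.02-fold. For the glucocorticoid list the median TPM was lower in replicate 2 (33.3 and 31.2), opposite to its median ratio. The other 25 lists, the receptor, rearrangement, double-positive and cell cycle lists among them, had medians between -0.30 and 0.22 on the log2 scale. With 1 library per pup, these differences compare the libraries and have no replicate check.

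**Figure D3:**
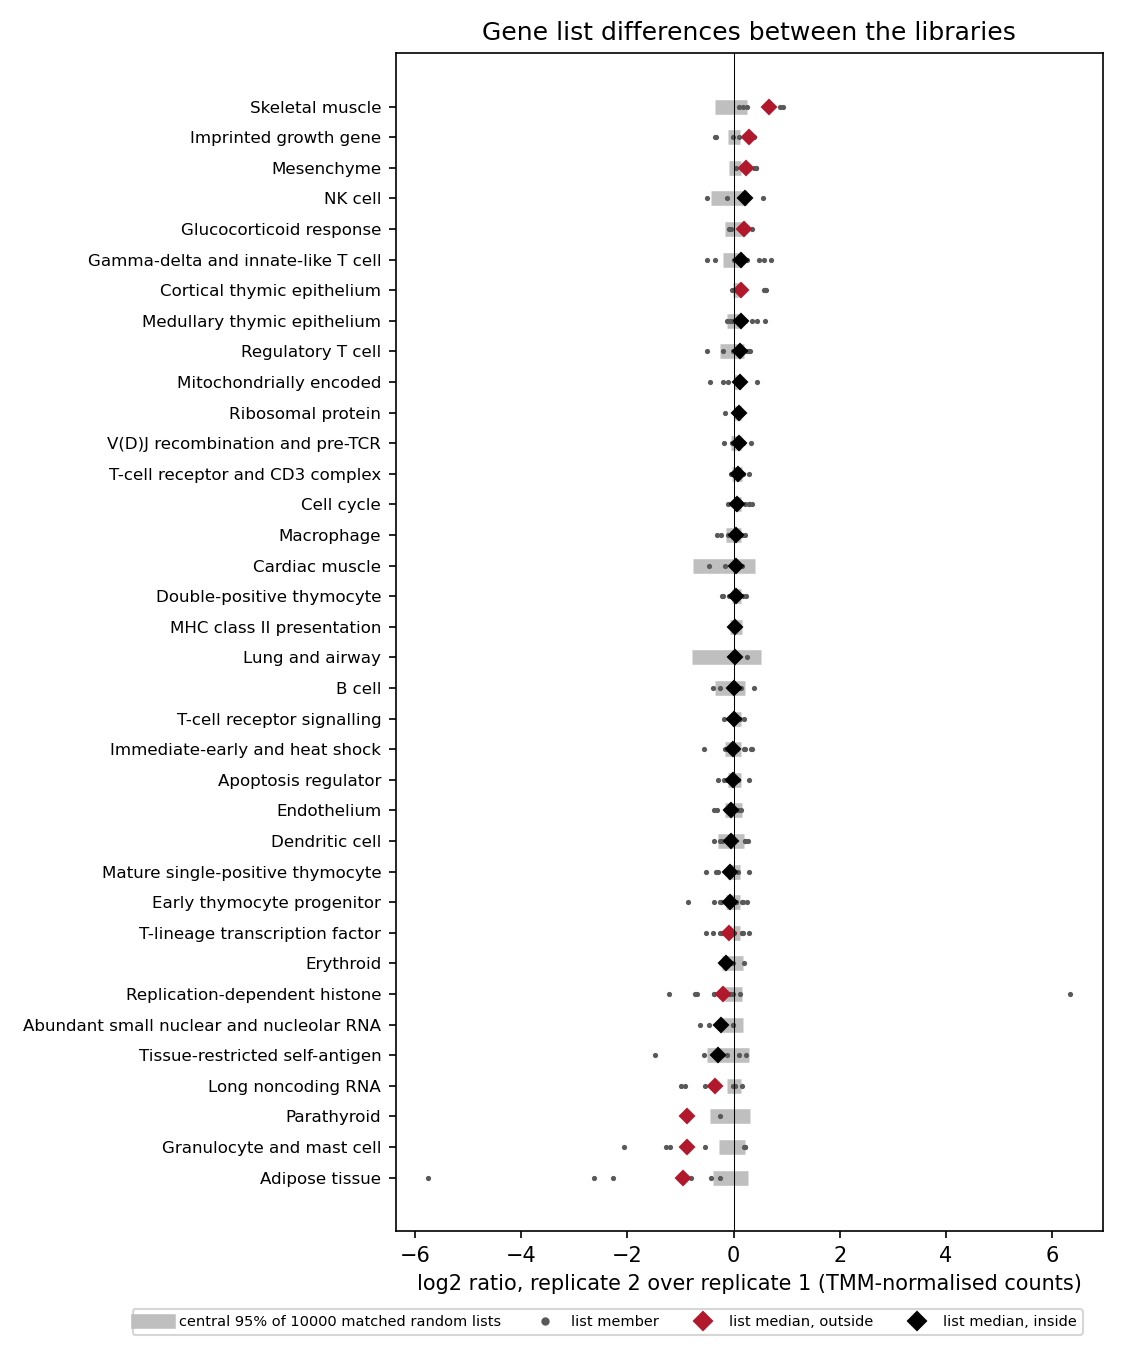
Log2 ratio of replicate 2 over replicate 1 for 36 gene lists, with each member (dots), the list median (diamonds, red where outside) and the central 95% of 10000 matched random lists (grey bars). Adipose tissue, at -0.96, has the lowest median and skeletal muscle, at 0.66, the highest.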

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

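The tests of medullary epithelium, of the length and GC trends and of mesenchyme share were chosen only after the result was seen. Rows whose identifier is only a number lie outside every comparison, yet held 41 counts in replicate 1 and 16.8 in replicate 2, above the 3 counts that an empty measurement allows. Of 26248 such rows 7 had a count, and 1 row held 32 and 14 counts.

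Krt4, Krt13 and Krt15 and the adipose, parathyroid and granulocyte lists were higher in replicate 1. Counting error and a spread common to all genes are argued against for the number of genes over 2-fold, since 0 of 100 simulated pairs reached the observed 191 (highest 17). That number covers all genes, so it does not bear on the keratins or the 3 lists singly. The adipose and granulocyte medians, -0.96 and -0.88, lay at percentiles 0.01 and 0 of matched random lists from the same libraries. These lists were picked out by the same percentiles, so the percentiles are no separate test of either explanation for them. At a mean count of at least 50 the adipose median was -0.61 (percentile 0.06) and the granulocyte median -0.70 (percentile 0). Parathyroid (-0.87, percentile 0.18) rests on 3 members. More medullary epithelium as a whole is argued against, since the medullary list had a median log2 ratio of 0.13 and its lowest member, Krt14, stood at -0.12. A rise of a small part of this epithelium could leave the list unmoved and was not tested. Squamous epithelium from a neighbouring organ stays open: 12 markers fixed before their values were seen had a median of -0.23 (percentile 3.49, 9 of 12 higher in replicate 1), short of the 0.50 in size set in advance, with Sprr3 at 37 and 2 counts and Krt6a at 6.38 and 2.84 TPM, but the most abundant, Sfn (49.6 and 54.9 TPM) and Krtdap (29.6 and 32.3 TPM), were not higher. Of these markers 9 were at 1 TPM or more in both libraries, so the thymus's own baseline may hide a small share.

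Long noncoding RNA was higher in replicate 1, with a median log2 ratio of -0.36. Removing the trends with transcript length and GC content left -0.11 (percentile 4.05, from 0.02). This met a rule for the trends as the explanation, written after the result was seen. The move came from the long Kcnq1ot1, which went from -0.92 to -0.11. The 6 other members had a median of -0.18 before and -0.22 after. Those at or below the list median, Malat1 (taken at 536 nt), Neat1 and Meg3, had a median of -0.54 before and -0.53 after. The trends thus took little from their ratios. Leaving out the member that moved most fixed this in advance for the rest, so it is no test of the trends. More nuclear, incompletely spliced RNA is a candidate explanation that stays open: within 2477 genes, retained-intron transcripts were lower in replicate 2 relative to coding transcripts by a median log2 difference of -0.40, with 80.4% of genes below 0, and 935 genes with transcripts of like length gave -0.43. Of 118 gene models of the TEC type (provisional models) or sense-intronic type, 109 were higher in replicate 1, at a median of -0.98 before and -0.95 after the trends were removed. The trends stay open for the list, and genomic DNA in the library was not separated from unspliced RNA here.

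Elastin, skeletal muscle and mesenchyme genes were higher in replicate 2. A larger share of mesenchyme alone stays open. The skeletal muscle list had a median log2 ratio of 0.66, or 0.46 at a mean count of at least 50. Both lay above the 0.42 of the highest of 10 mesenchyme genes, Pdgfra, as a rule written after the result required for refusing this explanation. However, 3 of the 7 muscle members lay within the mesenchyme range, so the list does not decide. Eln, at 3.01, lay far above that range, but is 1 gene. Vascular smooth muscle of a large vessel stays open too: 10 tested markers fixed before their values were seen had a median of 0.35 (percentile 100, 9 of 10 higher), below the 0.50 set in advance and far below the 8.05-fold of Eln. The most abundant of them, Mfap5 (46.4 and 53.1 TPM) and Emilin1 (40.1 and 40.1 TPM), are also made by fibroblasts, and 8 of the 11 were at 1 TPM or more in both libraries. Differences in tissue content were tested for the keratin and elastin patterns only, and since the labels name no difference between the pups, no biological explanation named by the design was tested for any of the 3 patterns.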

How the results depend on the processing

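Removal of the length and GC trends was chosen only after the result was seen. Detected genes, list genes detected and the number of lists outside the central 95% stayed within 1.5 times their values under every alternative run, and replicate 1 alone gave 14652 and replicate 2 alone 14292 detected genes. Genes over 2-fold numbered 1007 with spike-in scaling (30 and 977 by direction), 840 at a mean count of at least 10 (626 and 214) and 21 at 500 (20 and 1), and 190 with the trends removed. The lower minimum admits and the higher removes genes with more counting error. The spike-in shift rests on 659 and 427 counts, and its cause was not tested. Under spike-in scaling 13 of the 36 lists changed sign. Of the 11 lists outside, 3 did so, T-lineage transcription factors (0.60), replication-dependent histones (0.48) and long noncoding RNA (0.34), because all ratios moved together, and no list crossed the central 95%. The median DESeq2 gene-wise dispersion gave a coefficient of variation of 3.90%, and in the simulation it returned 4.78% for a true 11.7%. Pearson r was 0.967 with a pseudocount of 0.1. The spike-in share was 26.0 as TPM, against 13.6 CPM. The highest 10 genes held 6.50% of expected counts and 7.5% of TPM without mitochondrial and small RNA genes, by construction. The highest transcript was shared in 91.4% of genes at 1 TPM, 96.4% at 50 TPM and 99.4% where it led by 10 percentage points. The causes of the changes in r, in the spike-in share and in the transcript shares were not tested. Of the single list differences, TPM moved 3 more outside the central 95%: T-cell receptor signalling, medullary epithelium and the double-positive list, whose median turned from 0.036 to -0.083. The minimum of 50 counts moved 2 outside and left the parathyroid list, 1 of the 11, with too few members to be tested, and the trends moved 1 outside and 1 inside. That minimum also brought the adipose median from -0.96 to -0.61 and the granulocyte median from -0.88 to -0.70, both still outside. No paired analysis was possible because there is 1 group. Depth limits genes with few counts, such as Foxp3 and Il17a.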

Other observations

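T-cell receptor variable segments gave a view of the repertoire that the fixed lists did not cover. The segments named here were chosen after their values were seen. Of 21 beta-chain segments 20 were detected, led by Trbv13-2 at 332 ± 42.1 TPM, Trbv5 at 309.8 ± 3.03 TPM and Trbv16 at 269 ± 8.90 TPM (n = 2). Alpha-chain segments summed to 524 and 514 TPM against 3605 and 3633 TPM for beta-chain segments. Gamma-chain segments summed to 246 and 342 TPM, with Trgv2 at 131 and 194 TPM and Tcrg-V4 at 66.7 and 86.4 TPM, alongside the constant region Tcrg-C1 at 221 and 300 TPM. The highest delta-chain segment, Trdv2-2, was at 46.8 and 44.0 TPM.

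A hypothesis was that alpha-chain V segments nearer to the constant region Trac are used more in the newborn thymus. Across 94 segments with a count, 344 to 1792 kb from Trac on chromosome 14, Spearman rho of TPM with distance was -0.69 in replicate 1 and -0.67 in replicate 2, as a relation across segments, which are not independent. The nearer 47 segments held 76.2% and 76.4% of alpha-chain V segment TPM. The ranks of segments also matched between pups, with rho = 0.947. Copies named d or n lie at 850 kb or more from Trac, and division of reads between near-identical copies lowers such far segments and can feed this relation. In tests chosen only after the result was seen, 15 segments without such a copy gave rho of -0.82 in both libraries. With the TPM of copies summed over 46 segments, rho was -0.65 and -0.68 at the distance of the nearest copy, and -0.37 and -0.42 at that of the farthest. All values are negative, as the hypothesis needs, but how strong the relation is depends on how copies are treated.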
